A study of Mus musculus with 9 samples.

How the data were processed

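The data were gene-level RNA-seq tables from mouse R1 embryonic stem cells carrying a control hairpin (sh-ctrl), a hairpin against Pfkp (sh-Pfkp) or a hairpin against Lin41, whose gene is Trim71 (sh-Lin41), with 3 libraries per group. Per the labels, embryoid bodies were formed over 6 days by withdrawing LIF from cells in suspension, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. The submitters' processing notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM, with no version for HISAT2 or RSEM. The genome build, the annotation, the strand setting and the tool behind the authors' p-values are not given in the sources used here, so no coordinates are printed.

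The deposited read counts per gene are whole numbers, per the file headers one column per library. RSEM is named in the notes, so the counts may be estimated counts that the authors rounded. FPKM values per library were deposited beside the counts, per the file headers. The authors' deposited tables also hold a log2 ratio of the group mean FPKM, and a p-value with an FDR for each gene. Their filtered tables hold only genes with an FDR under 0.05 and an absolute log2 ratio over 1. Each full table listed 22322 genes, of which 4283 had 0 counts in all 9 libraries. The control values were identical in both tables, so all 9 libraries entered a single fit. Total counts ranged from 15495194 to 20607683 per library. A gene at 0 counts in a library has an upper limit of 3 counts, which covers counting error only.

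Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr by group, TMM scaling, a quasi-likelihood fit with 6 residual degrees of freedom, and Benjamini-Hochberg adjustment with a threshold of 0.05 and no minimum fold. Of the genes listed, 13158 were tested. Standard errors (SE) of log2 fold changes were the fold change divided by the square root of the F statistic. Levels are CPM, the read counts scaled by TMM-adjusted library size, as mean ± SD. The steps were tested on simulated data drawn from the means and depths of these libraries. In the simulated Pfkp comparison, with 12912 genes tested, 56% of 50 genes changed by 1.25-fold were recovered, 88% of those changed by 1.5-fold and 100% of those changed by 2-fold, and 17 of 12712 unchanged genes were called.

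The groups compared, the tests, 30 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members were tested on log2 CPM with camera (limma 3.58.1) at a preset correlation of 0.01. They were adjusted over the lists within a comparison, and tested again with an estimated correlation and with fry. With an estimated correlation camera also uses only the 6 residual degrees of freedom. Its p-values therefore rise even for lists whose estimated correlation lies under 0.01. Against control, the rule named Pfkp and Trim71, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM, a symbol that is not a predicted or clone name and non-overlapping groups, and up to 4 called members of each list with the smallest adjusted p. Between the knockdowns it took 5 in each direction and up to 2 members of each list. A list with no called member gave its most abundant one. Genes named outside that rule are marked as chosen after their values were seen, and some genes are not reported here. Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), other scaling, other filters, fits of 6 libraries, a 2-fold minimum, a fit with the replicate number as a block and the omission of each library. Planned pseudocount alternatives applied only to tables without counts and were not run.

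Replicate pairs had a median chi-square between 0.661 and 0.763 over genes with at least 50 counts, against 0.455 expected from counting noise, so no pair was treated as one library. The biological coefficient of variation was 0.0213. The replicate numbers come from the labels, which do not say what they mark. Deviations from the group means correlated between same-numbered sh-ctrl and sh-Pfkp libraries (r of 0.108, 0.307 and 0.449 across genes), so the numbers were taken to pair these libraries. Pairs with different numbers reached 0.143 between these groups and 0.402 between sh-Pfkp and sh-Lin41, so the pairing is not established. Same-numbered pairs with sh-Lin41 had r between -0.314 and 0.0344 and were not taken as paired. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.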

Results

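Gene expression was profiled by RNA-seq in 9 libraries of mouse R1 embryonic stem cells labelled as day 6 embryoid bodies, the aggregates that stem cells form in suspension when they begin to differentiate. There were 3 groups of 3 libraries, sh-ctrl, sh-Pfkp and sh-Lin41. The labels name no second hairpin against either gene and no rescue. An effect particular to a hairpin or its cell line therefore cannot be told apart from an effect of the knockdown. Pfkp encodes the platelet isoform of phosphofructokinase, a rate-controlling enzyme of glycolysis, and Lin41 is the protein of Trim71, an RNA-binding TRIM-NHL factor of stem cells. The series title describes Pfkp as a protein kinase for Lin41 in stem cell differentiation, and the design compares each knockdown with control. Total counts per library lay between 15495194 and 20607683. The first principal component held 42.1% of the variance of log2 CPM and the second 28.8%, and together they placed the 3 groups apart.

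Both targeted genes were lower in their own knockdown. Pfkp (ENSMUSG00000021196) had 248.3, 245 and 248 CPM in the 3 sh-ctrl libraries, 102.5, 101.2 and 104.9 CPM in sh-Pfkp and 232.6, 226.9 and 221.8 CPM in sh-Lin41. The means were 247.1 ± 1.83, 102.9 ± 1.89 and 227.1 ± 5.39 CPM (SD, n = 3). This was a log2 fold change of -1.27 (SE 0.0271, edgeR adjusted p = 5.4e-27, n = 3 per group) in its own knockdown and of -0.12 (SE 0.0243, adjusted p = 8.68e-05) in the Lin41 knockdown. Trim71 (ENSMUSG00000079259) had 273, 263.7 and 269.7 CPM in sh-ctrl, 349.6, 359.9 and 347.2 CPM in sh-Pfkp and 165.1, 157.7 and 155.9 CPM in sh-Lin41. The means were 268.8 ± 4.72, 352.2 ± 6.77 and 159.6 ± 4.89 CPM (SD, n = 3). Its log2 fold change was -0.75 (SE 0.0257, edgeR adjusted p = 1.32e-21) in the Lin41 knockdown and 0.39 (SE 0.0238, adjusted p = 4.06e-15) in the Pfkp knockdown.

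**Figure D1:**
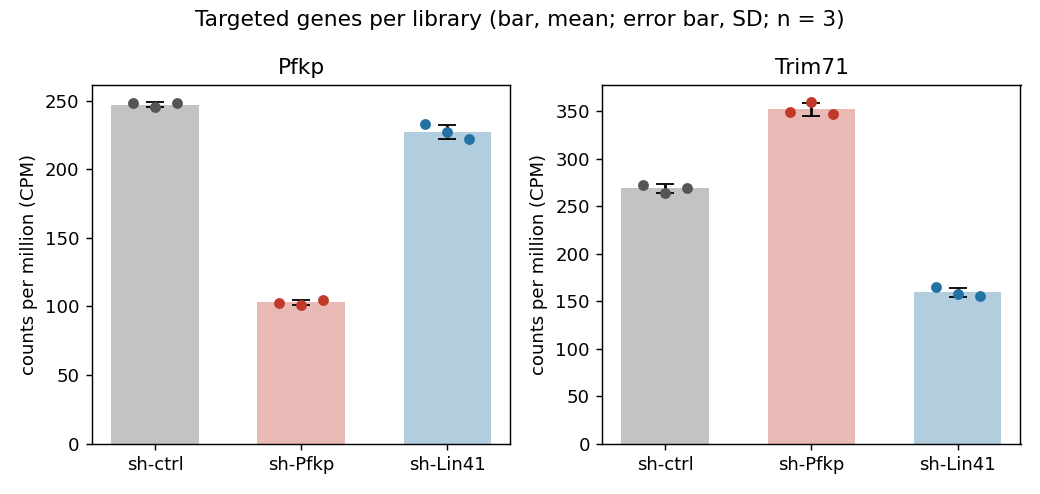
CPM of Pfkp and Trim71 in each library (points), with the group mean (bar) and SD (error bar) of 3 libraries. Pfkp was lowest in sh-Pfkp, at a mean of 102.9 CPM, and Trim71 was lowest in sh-Lin41, at 159.6 CPM.

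The libraries of all 3 groups carried high levels of pluripotency transcripts, and lineage marker levels differed between lists. All 25 members of the naive and core pluripotency list had at least 10 CPM in sh-ctrl, with a median of 200 CPM. In the same libraries 12 of 16 primitive streak markers, 10 of 14 definitive endoderm markers and 15 of 20 cardiomyocyte markers were under 1 CPM, as were 12 of 28 neuroectoderm and neuron markers and 13 of 25 extraembryonic endoderm markers. In each of these last lists 6 markers had at least 10 CPM. Pou5f1, Esrrb, T and Sox17 were chosen as examples after their values were seen. The pluripotency factor genes Pou5f1 and Esrrb had 891.9 ± 9.35 and 813.7 ± 8.68 CPM (SD, n = 3) in sh-ctrl, whereas T, the streak marker Brachyury, had 0.355 CPM and the endoderm factor gene Sox17 had 0.209 CPM. All libraries are labelled day 6 and no undifferentiated sample was among them, so how far the cells had differentiated was not tested.

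**Figure D2:**
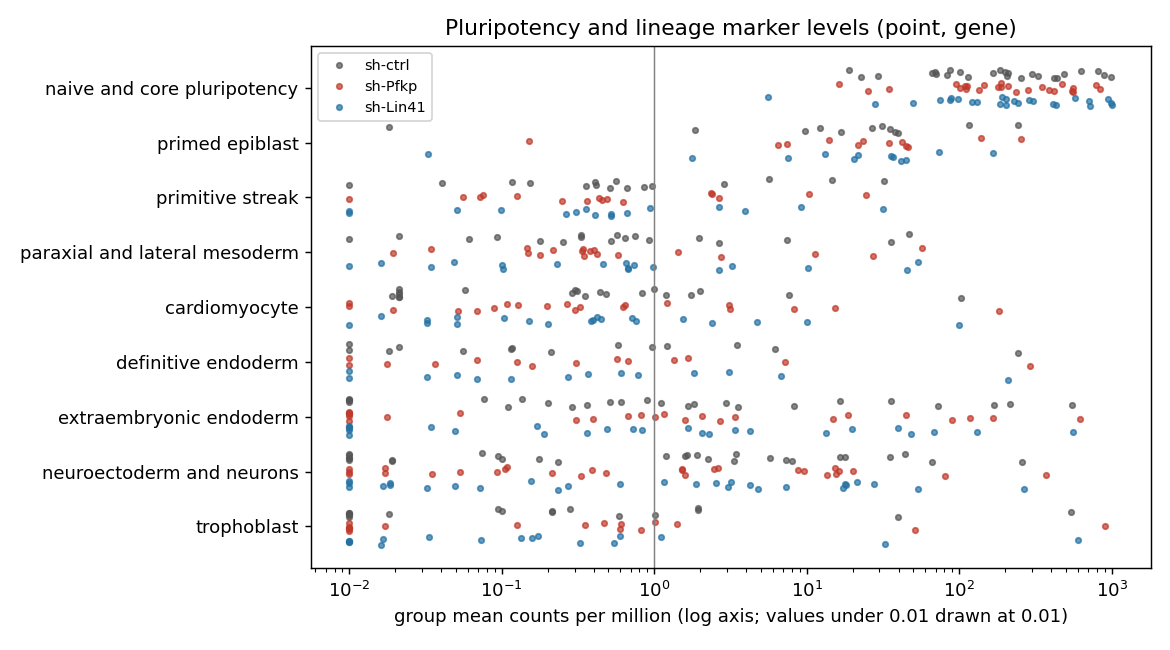
Mean CPM (log axis) of each member of 9 marker lists in sh-ctrl, sh-Pfkp and sh-Lin41, each over 3 libraries, with a line at 1 CPM. Pluripotency markers lie mostly above 10 CPM in each group, and 12 of 16 primitive streak markers lie under 1 CPM in sh-ctrl.

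In the Pfkp knockdown, genes of sugar uptake and glycolysis were lower than in control, together with hypoxia-response and stress-response genes. Of 21 glycolysis genes tested, 19 fell and 1 rose (median log2 fold change -0.44, camera adjusted p = 5.04e-09, and adjusted p = 0.0219 with an estimated correlation). Among them were the glucose transporters Slc2a1 (-0.78, SE 0.0153) and Slc2a3 (-0.59, SE 0.0143), the lactate exporter Slc16a3 (-1.31, SE 0.0311) and the triose-phosphate isomerase gene Tpi1 (-0.67, SE 0.0188). Of 14 hypoxia-response genes, 11 fell and 1 rose (camera adjusted p = 9.2e-06, and adjusted p = 0.0219 with an estimated correlation), including Bnip3, a mitophagy receptor (-1.35, SE 0.031), the oxygen-sensing hydroxylases Egln3 (-1.46, SE 0.0416) and Egln1 (-1.02, SE 0.0411), and Vegfa (-1.05, SE 0.0426). Of 15 genes of the integrated and ER stress response, 14 fell and none rose (camera adjusted p = 9.2e-06, and adjusted p = 0.0219 with an estimated correlation), among them Chac1 (-1.64, SE 0.0933), the serine synthesis genes Phgdh (-0.74, SE 0.0329) and Psat1 (-0.47, SE 0.0226), and Atf4 (-0.32, SE 0.0268).

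Cell-identity genes moved in both directions in the Pfkp knockdown. Of 25 pluripotency genes, 16 rose and 8 fell (camera adjusted p = 0.0271, and adjusted p = 0.216 with an estimated correlation). The NODAL co-receptor gene Tdgf1 fell from 984.4 ± 2.39 to 551.4 ± 10.4 CPM (SD, n = 3; log2 -0.84, SE 0.0177), while Klf2 (0.72, SE 0.0366), Gdf3 (0.70, SE 0.0356) and Sall4 (0.47, SE 0.025) rose. Of 16 tested feedback targets of WNT, NODAL and BMP signalling 9 fell and 3 rose, without a call for the list (camera adjusted p = 0.0822). The NODAL feedback genes Lefty1 (-1.35, SE 0.0609) and Lefty2 (-1.40, SE 0.0393) fell and the WNT feedback gene Notum (0.62, SE 0.0745) rose. Of 15 epithelial genes, 14 fell and none rose (camera adjusted p = 2.31e-05, and adjusted p = 0.0773 with an estimated correlation), among them Epcam (-0.48, SE 0.0319) and the claudin gene Cldn6 (-0.99, SE 0.0811). Of 11 primed epiblast genes 8 rose and 2 fell, without a call for the list (camera adjusted p = 0.0807). Otx2, a member of that list and a factor of the epiblast and forebrain, rose from 1.86 ± 0.337 to 7.40 ± 0.638 CPM (1.99, SE 0.17) and the neural factor gene Pax6 rose (1.08, SE 0.0983), whereas the neuronal RNA-binding protein gene Elavl3 fell (-1.53, SE 0.0639). Of 16 tested genes of the neuroectoderm list 5 rose and 6 fell, and that list was not called (camera adjusted p = 0.862). At least a 2-fold change was seen for 1 of those that rose and 5 of those that fell. Of 13 genes of the let-7 axis, 6 rose and 3 fell without a call for the list (camera adjusted p = 0.097). Mycn (0.92, SE 0.0321) and Hmga2 (1.16, SE 0.0915) were among those that rose. Of 12 feedback targets of FGF and ERK signalling 9 rose and 2 fell (camera adjusted p = 0.0199, and adjusted p = 0.216 with an estimated correlation), including Spry2 (0.61, SE 0.0462) and Spred1 (0.44, SE 0.0286).

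The largest rises in the Pfkp knockdown included stromal genes with few counts in the control libraries. Vcam1, an adhesion molecule, had 359 counts over the 3 sh-Pfkp libraries and 1 count over the 3 controls, a ratio of 332 with an exact counting interval from 59.2 to 13100. Col1a2 and Col3a1, fibrillar collagens, had ratios of 261 (46.5 to 10400) and 135 (37 to 1120), against 1 and 2 control counts. Col5a2 (3.52, SE 0.358), Thbs1 (3.50, SE 0.28) and Bgn (3.45, SE 0.307) rose as well. In the mesenchymal matrix list 7 of 15 tested genes rose and 5 fell, without a call for the list (camera adjusted p = 0.178), and 8 rose and 5 fell adjusted over the list alone. Pramel45 (2.84, SE 0.374) and Pramel19 (2.68, SE 0.409), members of a multicopy family whose reads can be shared between copies, completed the largest rises. Egr1, an immediate early transcription factor, had the largest fall among the genes the naming rule covers, from 67.23 ± 1.01 to 6.69 ± 0.177 CPM (-3.33, SE 0.064, edgeR adjusted p = 4.93e-28), followed by Gpr139 (-3.26, SE 0.419), Scnn1a (-2.94, SE 0.385), Cacna1h (-2.93, SE 0.123), Aph1b (-2.55, SE 0.336), Fam83f (-2.33, SE 0.287), Fbxo43 (-2.27, SE 0.355) and Acvrl1 (-2.25, SE 0.146). Of 13 tested immediate early genes, which respond to handling, 9 fell and 2 rose (3 rose and 9 fell adjusted over the list alone), with Fos at -1.87 (SE 0.158), and the list was not called (camera adjusted p = 0.0807).

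Among 13158 genes tested in the Pfkp knockdown, edgeR called 3721 higher and 3730 lower, with a median absolute log2 fold change of 0.33 among called genes. At least a 2-fold change was seen for 297 of the higher and 560 of the lower genes. The authors' deposited table, filtered on FDR and fold, holds 343 higher and 580 lower genes. Of these 923 genes 794 were tested here and 708 were called at 2-fold, and 149 genes called here at 2-fold are not among theirs. Markers of RNA quality moved too. Of 13 mitochondrially encoded transcripts 12 rose (camera adjusted p = 9.2e-06, and adjusted p = 0.229 with an estimated correlation), and 16 of 24 ribosomal protein genes fell (camera adjusted p = 0.0178, and adjusted p = 0.532 with an estimated correlation). Of 8 tested cardiomyocyte genes 5 rose, with Smyd1 (2.21, SE 0.171) as an example, and of 14 p53 response genes 10 rose and 4 fell, with Mdm2 (0.51, SE 0.0301) as an example. Each of these lists had a camera adjusted p = 0.0444, and adjusted p = 0.216 with an estimated correlation. With the replicate number as a block over all 9 libraries neither was called (camera adjusted p = 0.0566 for cardiomyocyte and 0.0648 for p53 response genes). The cardiomyocyte call was lost without sh-ctrl replicate 2 (0.0682), sh-Pfkp replicate 1 (0.0773), sh-Lin41 replicate 1 (0.0641) or sh-Lin41 replicate 3 (0.0543). The p53 call was lost without sh-ctrl replicate 1 (0.086), sh-ctrl replicate 2 (0.0682), sh-Pfkp replicate 3 (0.0705) or any 1 of the sh-Lin41 libraries (0.0575, 0.0565 and 0.0528), and the ribosomal protein call without sh-Pfkp replicate 1 (0.0646). Adjusted over the list alone, 6 neuroectoderm genes rose and 6 fell, and the counts of the other lists given for this knockdown, the mesenchymal and immediate early ones apart, were the same as over all genes. With limma-trend on log2(FPKM + 1) the split of calls moved to 2507 higher and 3802 lower.

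In the Lin41 knockdown, pluripotency genes were more often higher than lower relative to control. Of 25 pluripotency genes, 15 rose and 4 fell (median log2 fold change 0.22, camera adjusted p = 0.00119, and adjusted p = 0.132 with an estimated correlation). Zfp42, also called Rex1, rose from 420.1 ± 15.8 to 722.1 ± 7.12 CPM (SD, n = 3; 0.78, SE 0.0226), and Klf5 (0.86, SE 0.0279), Nanog (0.53, SE 0.0179) and Tbx3 (0.71, SE 0.0289) rose with it. In the primed epiblast list 4 of 11 genes rose and 4 fell, without a call (camera adjusted p = 0.845). The de novo DNA methyltransferase genes Dnmt3a (-0.65, SE 0.0345) and Dnmt3b (-0.54, SE 0.0278) fell, and Foxd3 rose (0.82, SE 0.077). The laminin genes Lamb1 (-1.31, SE 0.0326) and Lama1 (-0.71, SE 0.0296) fell in a list of extraembryonic endoderm genes in which 5 of 15 rose and 4 fell (camera adjusted p = 0.84). Of 15 epithelial genes 14 fell (camera adjusted p = 2e-06, and adjusted p = 0.0604 with an estimated correlation), including Cldn4 (-1.15, SE 0.0497) and the E-cadherin gene Cdh1 (-0.37, SE 0.0195).

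Of 21 glycolysis genes in the Lin41 knockdown 18 fell and 1 rose (median log2 fold change -0.38, camera adjusted p = 7.09e-08, and adjusted p = 0.0322 with an estimated correlation). Slc16a3 (-0.99, SE 0.0299), the lactate dehydrogenase gene Ldha (-0.46, SE 0.0143) and Pgam1 (-0.39, SE 0.0148) were among them. Of 14 hypoxia-response genes 10 fell and 1 rose (camera adjusted p = 2.02e-05, and adjusted p = 0.0362 with an estimated correlation), with Ddit4 (-1.20, SE 0.0387) and Bnip3 (-0.84, SE 0.0293) as examples. Of 25 proliferation genes 16 fell and 5 rose (camera adjusted p = 0.00967, and adjusted p = 0.174 with an estimated correlation). The G1 cyclin genes went apart, as Ccne1 (-0.58, SE 0.0259) and Ccnd3 (-0.51, SE 0.0233) fell and Ccnd2 rose (0.92, SE 0.0471).

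Of the 7 mRNAs described as Trim71 targets, 4 rose and 2 fell in the Lin41 knockdown, without a call for the list (camera adjusted p = 0.571). The splicing factor gene Mbnl1 (1.39, SE 0.0761) and the pocket protein gene Rbl1 (0.91, SE 0.0537) rose, and Egr1 fell from 67.23 ± 1.01 to 20.76 ± 0.863 CPM (-1.69, SE 0.0511). In the let-7 axis 8 of 13 genes fell and 3 rose (camera adjusted p = 0.191), with Lin28a at -0.39 (SE 0.0225) and Lin28b at -0.54 (SE 0.0587). Of 7 tested Hox genes 5 rose and none fell (camera adjusted p = 0.0471, and adjusted p = 0.302 with an estimated correlation). Hoxa10 rose from 0.934 ± 0.0225 to 6.68 ± 0.524 CPM (2.83, SE 0.189) and Hoxa9 from 0.312 ± 0.122 to 1.85 ± 0.306 CPM (2.54, SE 0.36). The Hox list lost its call without sh-Lin41 replicate 3 (adjusted p = 0.0625) and without sh-Pfkp replicate 1 (adjusted p = 0.0675).

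The largest rises in the Lin41 knockdown were those of the calcium channel gene Itpr2 (4.16, SE 0.372), Tm9sf5 (3.21, SE 0.22), Zan (3.01, SE 0.225), Hoxa10, Col1a2, Zscan4f (2.51, SE 0.101), Islr2 (2.50, SE 0.0943) and Gpr83 (2.47, SE 0.238). Col1a2 rested on 10 counts against 1 in control, a ratio of 8.75 with an exact counting interval from 1.24 to 380, and lost its call without sh-ctrl replicate 1 (adjusted p = 0.0851), sh-ctrl replicate 3 (adjusted p = 0.0898) or sh-Lin41 replicate 1 (adjusted p = 0.151). Zscan4f, Zscan4c and Zscan4d, markers of the 2-cell-like state, are near-identical copies whose reads may be split between them. The largest falls were those of Cd109 (-2.77, SE 0.257), the vasodilator peptide gene Adm (-2.49, SE 0.172), Fbxo41 (-2.44, SE 0.213), Ppp1r3c (-2.40, SE 0.319), Dlx3 (-2.28, SE 0.14), Cdc42ep1 (-2.23, SE 0.315), Ier3 (-2.23, SE 0.106) and the Y-linked Uba1y (-2.12, SE 0.0801).

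Among 13158 genes tested in the Lin41 knockdown, edgeR called 3545 higher and 3596 lower, of which 268 and 292 changed at least 2-fold. The authors' deposited table, filtered on FDR and fold, holds 224 higher and 249 lower genes. Of these 473 genes 442 were tested here and 419 were called at 2-fold, and 141 genes called here at 2-fold are not among theirs. All 13 mitochondrially encoded transcripts rose (camera adjusted p = 1.21e-07, and adjusted p = 0.251 with an estimated correlation), and of 13 tested immediate early genes, which respond to handling, 8 fell and 1 rose (camera adjusted p = 0.00967, and adjusted p = 0.174 with an estimated correlation). Adjusted over the list alone, 16 pluripotency genes rose and 4 fell, and 1 epithelial gene rose and 14 fell. The counts of the other lists given for this knockdown, the FGF and ERK feedback list below apart, were the same as over all genes.

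**Figure D3:**
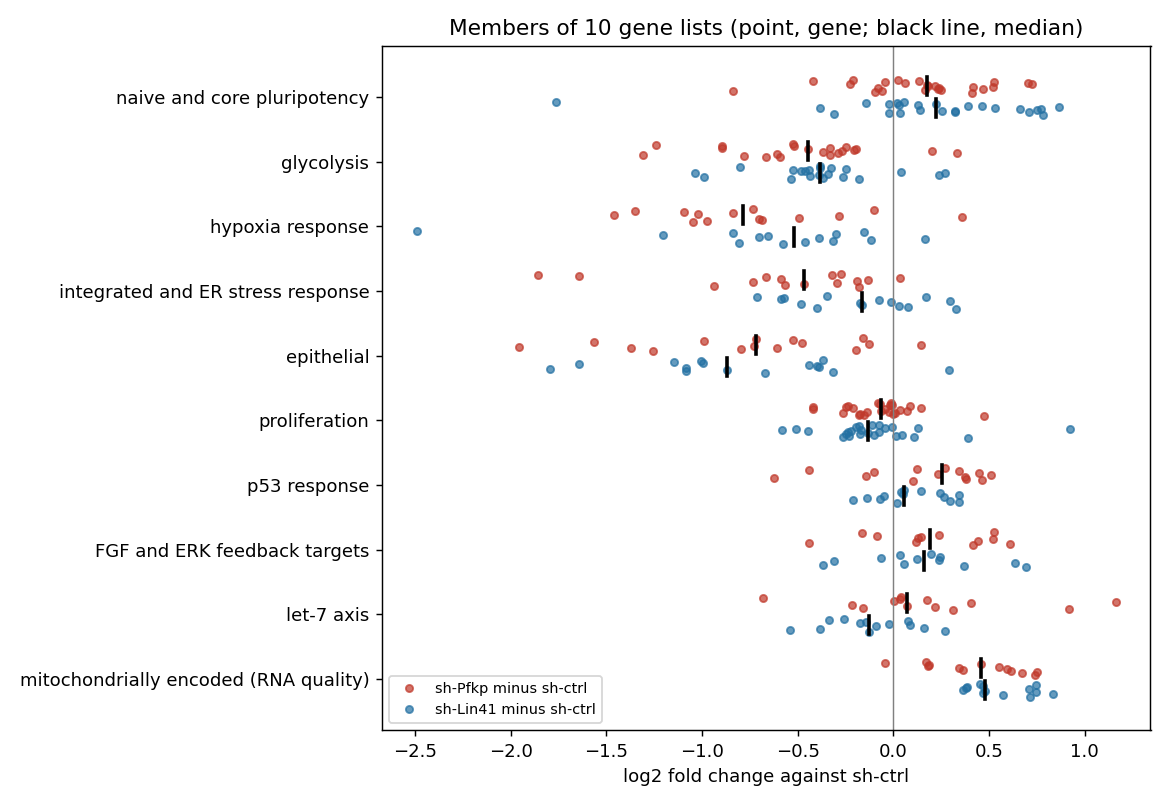
Log2 fold changes against sh-ctrl of the tested members of 10 gene lists in the Pfkp and Lin41 knockdowns (points, genes; black lines, medians). The median of the glycolysis list was -0.44 in the Pfkp knockdown and -0.38 in the Lin41 knockdown.

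Set directly against each other, the knockdowns differed in genes of the integrated and ER stress response. Of 15 stress-response genes 11 were lower and 1 was higher in sh-Pfkp than in sh-Lin41 (camera adjusted p = 0.0139, and adjusted p = 0.319 with an estimated correlation), with Psat1 at -0.50 (SE 0.0223) and Atf4 at -0.49 (SE 0.0262). Of 13 let-7 axis genes 9 were higher and 3 lower in sh-Pfkp (camera adjusted p = 0.0275, and adjusted p = 0.331 with an estimated correlation), among them Lin28a (0.60, SE 0.0221) and Mycn (0.64, SE 0.0305). Of 25 pluripotency genes 8 were higher and 14 lower in sh-Pfkp, without a call for the list (camera adjusted p = 0.204). Adjusted over the list alone, 8 were higher and 15 lower, and the stress and let-7 counts were the same as over all genes. Tdgf1 (-0.87, SE 0.0176) and Klf4 (-0.69, SE 0.0245) were lower there, and Dnmt3a (0.93, SE 0.0333) and Dnmt3b (0.61, SE 0.0274) were higher. Egr1 (-1.64, SE 0.0767), Rbl1 (-1.01, SE 0.0535) and Ccnd2 (-1.34, SE 0.0489) were lower in sh-Pfkp. Lists that fell in both knockdowns were not called here. Of 21 glycolysis genes 12 were lower and 4 higher in sh-Pfkp (camera adjusted p = 0.175). For hypoxia-response genes these counts were 7 and 3 of 14 (camera adjusted p = 0.204), and for epithelial genes 3 and 6 of 15 (camera adjusted p = 0.405).

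The largest differences towards sh-Pfkp were those of the stromal genes Vcam1 and Col3a1, with 2 counts each over the 3 sh-Lin41 libraries, Bgn (5.09, SE 0.371), Col1a2 (4.85, SE 0.318) and Col5a2 (3.71, SE 0.354). Those towards sh-Lin41 were Zan (-4.08, SE 0.256), the kidney and midbrain factor gene Pax2 (-2.63, SE 0.27), Aph1b (-2.47, SE 0.333), Ptprd (-2.31, SE 0.134) and the sodium channel gene Scn9a (-2.24, SE 0.221). Between the knockdowns edgeR called 3603 genes higher and 3652 lower in sh-Pfkp, of which 193 and 398 differed at least 2-fold.

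Many genes were called in both knockdowns against the same 3 control libraries. Of the genes called in both, 3833 had the same direction and 918 the opposite one. Independent lists of these sizes would share 1002.5 higher and 1019.4 lower genes, where 1932 and 1901 were found. Up to 2 genes were called in both in 20 simulated sets of unchanged groups. Unchanged groups have few calls to share, so that number does not measure what shared controls add to the overlap. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.56. Shared controls alone gave a mean r of 0.53 in the simulation, so r does not separate these data from unchanged groups. The covariance was 0.146 against a simulated mean of 0.0157, a difference of 0.131. The 3 controls are too few to be split into sets of 2, so part of the excess in shared calls may come from the shared controls. Bnip3, Slc16a3, Lefty1, Lefty2, Egr1 and Elavl3 fell in both knockdowns, and Zscan4f, Foxd3, Spry4 and Spred1 rose in both. The FGF and ERK feedback list, which holds Spry4 and Spred1, was not called in the Lin41 knockdown, where 6 of 12 genes rose and 2 fell (camera adjusted p = 0.0814), or 6 and 3 adjusted over the list alone.

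**Figure D4:**
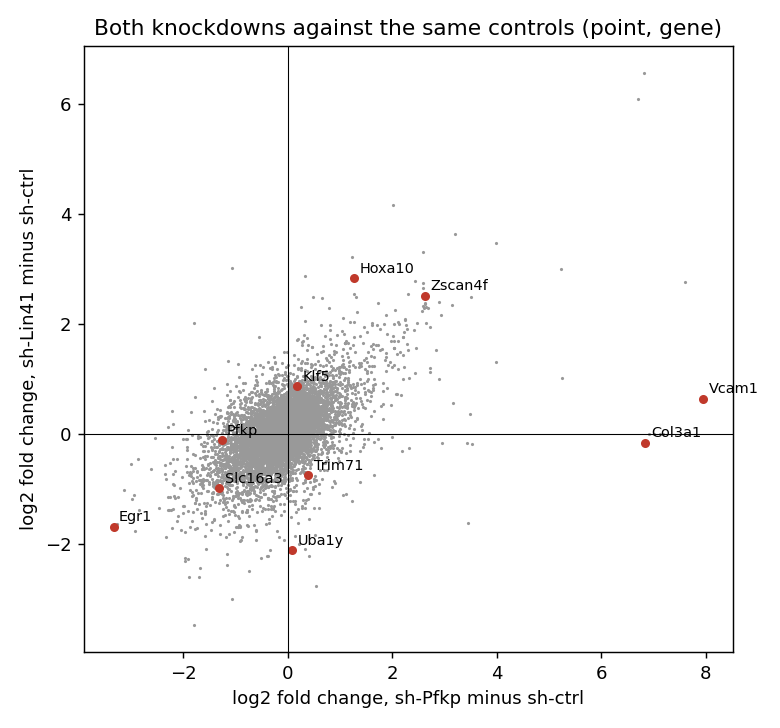
Log2 fold change in the Lin41 knockdown against that in the Pfkp knockdown, each against the same 3 sh-ctrl libraries (points, 13158 genes; named genes in red). Egr1 lies low on both axes, and Vcam1 and Col3a1 lie far to the right, at fitted values that rest on 1 and 2 control counts.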

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

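The limits of 1.2-fold and the omission of mitochondrially encoded genes were chosen after seeing the data. The calls against control and between the knockdowns kept within 1.5 times of 7451, 7141 and 7255 genes under the other scalings, filters and tests run. The exceptions were minimum folds, which by construction pass fewer genes. A 2-fold minimum gave 857 genes for Pfkp, 560 for Lin41 and 591 between the knockdowns, and a test against 1.2-fold (edgeR glmTreat) gave 2772, 2262 and 2449. DESeq2 called 6536, 6125 and 6275 genes. With limma-trend on log2(FPKM + 1) the calls between the knockdowns were 2409 higher and 3490 lower in sh-Pfkp, against 3603 and 3652. Without the mitochondrially encoded genes, edgeR called 7477, 7144 and 7253. Leaving out each library in turn gave 6876 to 7550, 6447 to 7176 and 6716 to 7299 calls. Pfkp and Trim71 kept their directions and calls with other size factors, a mean CPM filter, DESeq2, the replicate block and each library left out, the settings in which they were recomputed. Leaving out a library moved the correlation of both knockdowns between 0.528 and 0.574, and the cause was not tested.

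The replicate numbers were taken to pair the sh-ctrl and sh-Pfkp libraries, which the labels do not state. The replicate block was fitted over all 9 libraries, those of sh-Lin41 included, so its results do not isolate the pairing of sh-ctrl with sh-Pfkp. For Pfkp against control the replicate block gave 7435 calls and 8 called lists, against 10 without it. The cardiomyocyte and p53 response lists lost their calls, and the block changed no other call of a list or named gene there. In the comparisons with sh-Lin41 no same-numbered pair had r over 0.1, so those libraries share only a number, and 4 of all 9 libraries matched best with their own number. The replicate block gave 7109 calls for Lin41 and 7196 between the knockdowns. It gave 7 called lists for Lin41, where the Hox list was lost (0.0715), and 1 between the knockdowns, where the let-7 axis was lost (0.0546).

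With an estimated correlation, 3 lists passed for Pfkp, 2 for Lin41 and 0 between the knockdowns (3 at an unadjusted camera p under 0.05). That setting also lowers the degrees of freedom to 6, so fewer passes need not mean correlated genes. The hypoxia-response list had an estimated correlation of -0.0166, yet its unadjusted camera p for Pfkp rose from 1.07e-06 to 0.00204. For the mitochondrially encoded list the estimated correlation was 0.501. Fry, which tests whether a list moves one way and does not compare it with other genes, passed 24, 26 and 23. Leaving out a library gave 8 to 10, 7 to 8 and 2 to 5 lists. Between the knockdowns it was 4 without each sh-ctrl library in turn and 5 without sh-Lin41 replicate 1. The cause of these moves was not tested. Among named genes, 22 tests lost a call, 1 gained one and 3829 did not change side, and no direction was reversed.

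The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. Splits other than the real one mix both groups, so the group difference enters their residual spread and they call few genes by construction. Their low counts therefore say nothing about chance. In these fits the real split called 7412 genes for Pfkp, 7159 for Lin41 and 7229 between the knockdowns, the highest other split, those that part every same-numbered pair included, called 0 with edgeR (73 to 123 genes at an unadjusted p under 0.05 over the other splits), and 1 of the 10 splits, the real one, called as many.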

Other observations

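All tests in this part were chosen after the pattern they address was seen. For the fibroblast marker tests, only the values of the markers themselves were still unread. Among 1366 Gene Ontology process terms of the deposited annotation, camera called 14 in the Pfkp knockdown, 3 in the Lin41 knockdown and 28 between them. With an estimated correlation camera called 0 in each, where 105, 59 and 100 terms had an unadjusted p under 0.05. That setting also uses only the 6 residual degrees of freedom, which makes a pass over 1366 terms hard to reach. The 0 calls therefore do not show that correlation between genes undoes the calls. For ribosome biogenesis between the knockdowns the estimated correlation was 0.0059, under the preset 0.01, yet the unadjusted camera p rose from 1.57e-12 to 0.000215. Of 24 cholesterol biosynthesis genes, 18 fell and 2 rose in the Pfkp knockdown (camera adjusted p = 0.00187, and adjusted p = 0.572 with an estimated correlation). In the Lin41 knockdown 14 fell and 4 rose without a call (adjusted p = 0.214). Insig1, a sterol sensor, had log2 fold changes of -0.64 (SE 0.0415) in the Pfkp knockdown and -0.44 (SE 0.0402) in the Lin41 knockdown. Of 99 ribosome biogenesis genes, 72 were higher and 6 lower in sh-Pfkp than in sh-Lin41 (camera adjusted p = 2.15e-09, and adjusted p = 0.294 with an estimated correlation). Against control 57 rose and 4 fell in the Pfkp knockdown (adjusted p = 0.000182, and adjusted p = 0.572 with an estimated correlation), and 16 rose and 45 fell in the Lin41 knockdown without a call (adjusted p = 0.301). Of 16 genes of translation initiation complex formation, 13 fell and none rose in the Lin41 knockdown (adjusted p = 0.0312, and adjusted p = 0.886 with an estimated correlation), among them Eif3b (-0.32, SE 0.0188) and Eif5 (-0.31, SE 0.0195).

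The library of sh-ctrl replicate 3 held 49 counts of Slc1a2 and 32 of Sparcl1, where the highest count in another library was 2 and 1. These genes were chosen after their values were seen.

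Stromal and inflammatory transcripts appeared in all 3 sh-Pfkp libraries. Of 37 fibroblast markers written down before their values were read, 17 were under 0.5 CPM in the other groups. Of these, 6 (35.3%) were above every other library in all 3 sh-Pfkp libraries, against 4.15% of all 4814 low genes. In 1000 random gene sets of matched level at most 4 were. The 6 were Tnc, Col8a1, Col14a1, Ccl7, Cxcl1 and Mmp3. They had few counts over the 3 sh-Pfkp libraries, from 10 for Mmp3 (0.177 CPM) to 39 for Col14a1 (0.698 CPM). The random genes were drawn independently of one another, whereas markers of a cell type can rise together. The comparison therefore shows only that these low markers rose more often than unrelated genes of that level. Fibroblast RNA or cells may be present in these libraries, which the comparison cannot decide. Of the other 20 markers, however, Fap had 0 counts in every library and the rest were at 0.5 CPM or more in sh-ctrl, sh-Lin41 or both. Of these 19, Ddr2 (2.19 CPM against 0.713 CPM in sh-ctrl) and Fbln2 (3.03 against 1.92 CPM) were above every other library in all 3 sh-Pfkp libraries, 3 were below every other library, Loxl2 (18.5 against 53.8 CPM), Gas6 (11.1 against 16.8 CPM) and Fstl1 (42.8 against 53.5 CPM), and the rest were neither. The abundant collagen gene Col1a1 had 6.49 CPM against 1.87 CPM, and per the labels the stem cells grew on gelatin. Cells of the culture that took on a stromal state would raise the same 6 markers, and both cannot be told apart because the sh-Pfkp hairpin and these transcripts coincide.

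Uba1y and Zfy1 fell in the Lin41 knockdown, by log2 fold changes of -2.12 and -1.86. Loss of the whole Y chromosome is argued against by the other tested Y genes, whose median was -0.0694, with Ddx3y at 0.07 and Eif2s3y at -0.04. A change limited to part of the chromosome may account for it. Both genes were chosen after they were seen to fall, so their difference of 0.26 cannot decide this, and positions were not examined. A deletion and lower transcription cannot be told apart from expression alone.

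Both knockdowns moved many genes the same way against the shared controls. Chance error of the 3 control libraries is argued against by the covariance of 0.1463, above the highest of 20 simulated sets, 0.0183. The covariance exceeded the simulated mean by 0.1307. A state of the control cultures that all 3 share may account for this in whole or in part, and it cannot be told apart from a shared biological effect of both knockdowns because a single control group was analysed here.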
